A study of Saccharomyces cerevisiae with 104 samples.

How the data were processed

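The 104 samples comprised 100 ChIP-exo samples with 25 target labels, not analysed here, and 4 RNA-seq libraries, each with a table of gene abundances. The labels give the same growth, treatment and extraction texts for every sample. The extraction text describes chromatin immunoprecipitation, and the treatment text names H2O2 for all samples, so no RNA-seq library could be assigned to a condition, strain or replicate. All samples were left unassigned, and library numbers were given in accession order as names only.

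Each table listed 7108 genes with position, coverage, FPKM and TPM. Coverage, a signal, was deposited as mean read depth per gene, per the file headers. FPKM was deposited by the authors per the file headers, and was a constant multiple of coverage within a table. TPM was deposited by the authors on a scale that summed to the same total in each library with ribosomal RNA included, so a larger share of ribosomal RNA lowers the TPM of every messenger. The genome build was sacCer3, and BWA, Picard and SAMtools were used, per the submitters' processing notes, which cover ChIP-exo and RNA-seq together. The aligner and abundance estimator of the RNA-seq were not given in the sources used here, nor was the strandedness of the libraries, so overlapping and antisense genes and near-identical copies are uncertain. No read counts were part of these tables. Coverage times gene span gave 302.3, 218, 236 and 189.6 megabases for libraries 1 to 4, and no sampling intervals were computed. An entry of 0 can be a failed estimate, so such genes are described as listed at 0.

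Gene names came from the tables. A RefSeq gene table matched 6011 identifiers, of which 5997 had equal start positions, and gave the protein-coding class. Structural RNAs were 381 entries and mitochondrial genes 55. No gene name was repeated. GC content was not examined because no genome sequence was used here.

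Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Before the data were examined, 25 gene lists, the measures, their alternatives and the rule for naming genes were fixed. TPM values were transformed as log2(TPM + 1), which understates differences of low genes, and genes with a median TPM of at least 1 were kept (6400 genes, with 708 left out). For each list and library, the median over members of the difference from the gene's 4-library median was taken. It was compared with 10000 random lists of the same size matched on mean level in 20 bins. These were drawn from all 6400 genes, structural and mitochondrial RNA included. The percentile describes these libraries and is not a test of conditions, and no p-values were computed. A list needed at least 3 tested members. The difference from a 4-library median understates a shift in 1 library that holds a middle value, and moves the other libraries the opposite way. A shift in an outer library that stays outer leaves the median unchanged. On simulated data, 5 lists of 40 genes were shifted by 1 log2 unit in 1 middle library of the 6400-gene table. All were called there, with relative differences of 0.36 to 0.58 where 0.5 was the arithmetic value. No outer library was shifted. Of 400 unshifted list-library values, 95.5% lay inside the central 95%. The unshifted lists were random draws with independent noise, so that share follows from the setup. It gives no error rate for the fixed lists, whose members can vary together. With 1 library left out, the middle of 3 libraries sits at 0 for most lists, so most losses of a call there follow from the measure.

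The 92 named genes followed the fixed rule. It took the 10 nuclear protein-coding genes of highest median TPM, and the 12 with the largest range of log2(TPM + 1) among those with a median TPM of at least 10. It added the 2 members of largest range from each list at the same minimum, 16 genes set in advance, and all members of the marker and mating lists. Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum median TPM of 10, median-ratio scaling, FPKM, TPM rescaled without mitochondrial and structural RNA, and each library left out in turn. Chosen after seeing the data were random lists matched also on gene length in 5 bins, treatment of 10 reading frames that overlap ribosomal RNA, structural RNA ratios without those frames, and list differences for each of the 6 library pairs. A share or correlation was taken to have moved where it changed by more than 1 SD over the libraries or pairs, and a count where it changed by more than 1.5 times. A library was marked as far from the others by Dixon's ratio with a critical value of 0.829 for 4 values.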

Results

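The series holds samples of the budding yeast Saccharomyces cerevisiae. In 100 of them ChIP-exo was used, which maps protein-DNA contacts by trimming immunoprecipitated DNA with an exonuclease. These carried 25 target labels, mostly of the transcription machinery. Some labels, such as Rpb1 and Rpo21, name the same protein, and the list of targeted proteins used below holds 21. These 100 samples were not analysed here. The remaining 4 samples were RNA-seq libraries of total RNA and are called library 1 to library 4, numbers that only name them. By its title and design text, the study asked how RNA polymerase II stalls after acute hydrogen peroxide stress. The labels attach a single protocol to all samples (growth at 25 °C and treatment with 0.3 mM H2O2 for 6 min) and name no treated or untreated RNA-seq library. Each library is therefore described on its own, no groups were compared, and no replicate error exists for any value. Values in series are given in the order of libraries 1, 2, 3 and 4.

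Messenger RNA made up very different parts of the libraries. The 5989 nuclear protein-coding genes held 46.9, 12.2, 21.2 and 5.77% of TPM, the length-normalised abundance scale, and structural RNAs, the ribosomal, transfer, nucleolar and spliceosomal RNAs, held 47.5, 86.7, 74.4 and 89.5%. The 5.8S rRNA, the small RNA of the large ribosomal subunit, held 40.6, 69.7, 68.3 and 75.8% of TPM. The 5S rRNA, transcribed by RNA polymerase III, held 0.230, 6.06, 0.410 and 6.15%. SCR1, the RNA of the signal recognition particle, held 0.324, 1.55, 0.253 and 0.944%, and small nucleolar and nuclear RNAs held 1.20, 3.45, 1.87 and 3.29%. RDN5-3, a 5S rRNA gene (chromosome 12, 472465 to 472583), stood at 29.6, 1112, 42.0 and 791 TPM, and the small nucleolar RNA SNR10 (chromosome 7, 345986 to 346230) at 5.08, 1325, 753 and 1211 TPM. The 5S genes are near-identical copies, so the value of any single copy is uncertain.

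**Figure D1:**
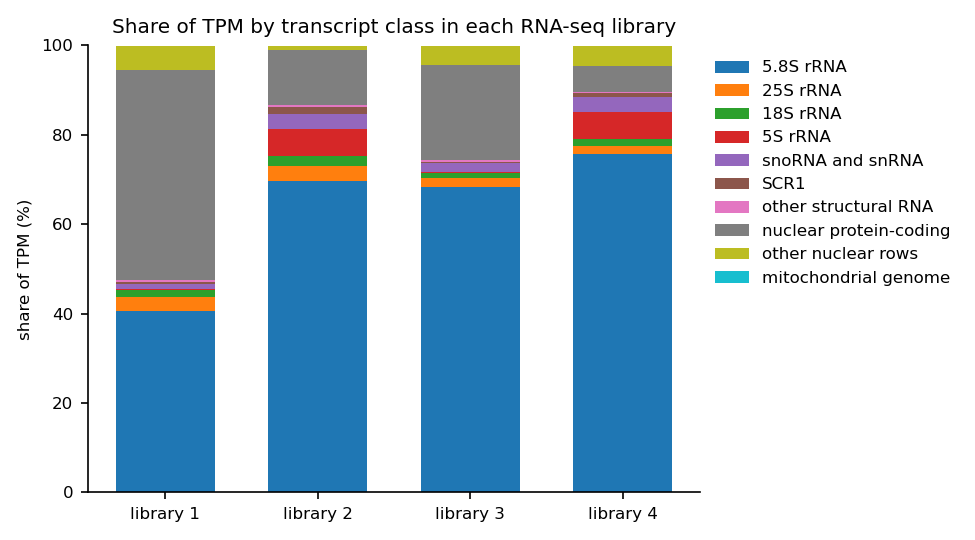
Share of TPM (%, y axis) held by each transcript class in the 4 RNA-seq libraries (x axis), as stacked bars. Protein-coding genes held 46.9% in library 1 and 5.77% in library 4.

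Depth over messenger RNA followed these shares. Coverage times gene span summed to 302.3, 218, 236 and 189.6 megabases over all genes and to 232, 72.3, 137 and 41.4 megabases over nuclear protein-coding genes. The median protein-coding gene had a coverage of 12.8, 3.70, 8.17 and 2.26, and 3551, 1042, 2485 and 594 protein-coding genes reached a coverage of 10. The median gene in library 4 therefore rested on the fewest reads, although single genes such as TDH3 had their lowest coverage in library 3.

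Apart from RRT15, described last, the most abundant messengers encoded glycolytic enzymes, an elongation factor, oxidoreductases and a metallothionein. Values relative to the median gene are a gene's difference from its own 4-library median, less the median such difference in that library. They compare changes between libraries, not expression levels between genes. Relative to the median gene, the glycolytic FBA1 stood at -0.95, 1.15, -1.15 and 0.42 log2 units and ADH1 at -0.96, 0.67, -0.67 and 0.33. OYE2 stood at 0.66, -0.55, 0.55 and -0.71, so it differed in the opposite direction. TDH3, a glyceraldehyde-3-phosphate dehydrogenase (chromosome 7, 882812 to 883810), stood at 1896, 2266, 995 and 929.8 TPM. The enolase ENO2 (chromosome 8, 451327 to 452640) had 2580.1, 1579, 1173 and 560.4 TPM, the aldolase FBA1 (chromosome 11, 326408 to 327487) had 1175, 1133, 484 and 384 TPM, and the alcohol dehydrogenase ADH1 (chromosome 15, 159548 to 160594) had 1845, 1282, 1072 and 572 TPM. TEF2 (chromosome 2, 477671 to 479047) and TEF1 (chromosome 16, 700594 to 701970), which encode the same elongation factor and cannot be separated with certainty, reached 1848, 1079, 854 and 413 TPM and 1735, 1024, 806 and 392 TPM. OYE2, an NADPH oxidoreductase (chromosome 8, 462502 to 463704), had 5188, 504, 2267 and 252 TPM, and the reductase GRE2 (chromosome 15, 43694 to 44722) had 3189.8, 279, 1959 and 188 TPM. The metallothionein CUP1-1 (chromosome 8, 212535 to 212720), present in repeated copies and so uncertain, had 3462, 401, 1543 and 202 TPM. RRT15, a short reading frame beside the ribosomal DNA (chromosome 12, 490406 to 490594), was listed at 3133, 3199, 1807 and 1733 TPM. Its median of 2470 TPM was the highest of the nuclear protein-coding genes, and it is counted among them. Relative to the median gene it stood at -1.22, 0.97, -0.93 and 0.91. Whether its signal comes from a messenger was not tested.

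Nearly all genes differed between the libraries on the TPM scale. Of 6400 genes with a median TPM of at least 1, 6286 spanned at least 2-fold on the log2(TPM + 1) scale, with a median range of 3.01. The median gene lay 1.61, -0.54, 0.54 and -1.37 log2 units from its own 4-library median. After each library was divided by its median ratio to the gene means, 2715 genes still spanned 2-fold and the median range was 0.88. Across the 6400 genes, which are not independent replicates, Spearman correlations were 0.757 for libraries 1 and 2, 0.952 for 1 and 3, 0.760 for 1 and 4, 0.793 for 2 and 3, 0.900 for 2 and 4, and 0.818 for 3 and 4. The SD of the difference in log2(TPM + 1) was, in the same order of pairs, 1.21, 0.58, 1.22, 1.01, 0.58 and 0.95.

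Gene lists are described below by their relative difference. This is the median over members of a library's log2(TPM + 1) minus the gene's 4-library median, less the same value for random lists of like expression level. A list stood apart where it fell outside the central 95% of 10000 random lists. Members counted as above the median gene had a positive value relative to it, as defined above, whatever their expression level. Libraries 2 and 3 held the middle values for 5598 of the 6400 genes, so their differences mirror each other by construction and do not count as separate observations. In all, 46 of 96 list-library values stood apart, 24 higher and 22 lower, and 15 lists stood apart in at least 1 library. These positions describe libraries relative to one another, not conditions.

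**Figure D2:**
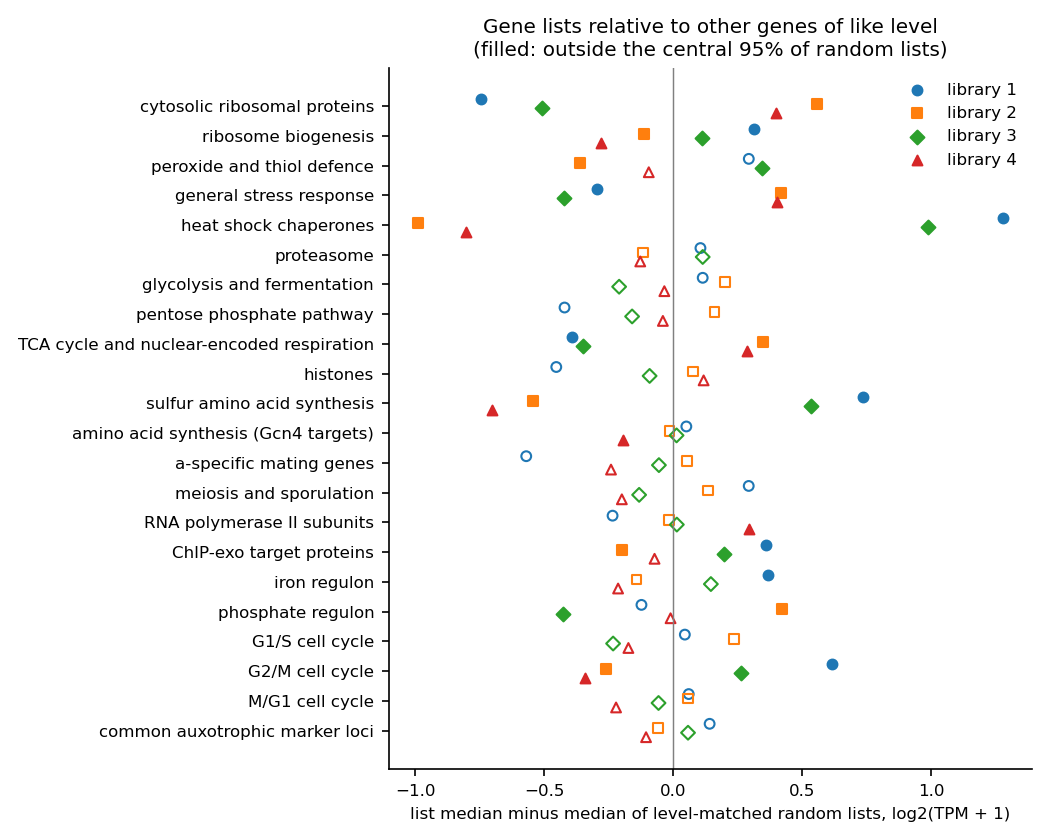
Relative difference of 22 nuclear gene lists (x axis, log2(TPM + 1) units) in the 4 libraries, with filled symbols outside the central 95% of random lists. Heat shock chaperones ranged from -0.99 in library 2 to 1.28 in library 1.

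Genes for sulfur uptake and methionine synthesis were among the most variable. The sulfur amino acid list stood apart in each library, at 0.74, -0.54, 0.54 and -0.70, with 20, 5, 20 and 2 of 25 members above the median gene. Left-out libraries kept the calls in libraries 1 and 4 but moved the values, to between 0.19 and 1.37 in library 1 and between -1.11 and -0.25 in library 4. These genes held 0.716, 0.0568, 0.292 and 0.0244% of TPM. The S-methylmethionine permease MMP1 (chromosome 12, 17956 to 19707) stood at 336, 4.54, 130.4 and 1.18 TPM, and STR3, cystathionine beta-lyase (chromosome 7, 154615 to 156012), at 295, 3.58, 138 and 1.83 TPM. MET6, methionine synthase (chromosome 5, 339864 to 342167), had 618, 25.9, 207 and 6.18 TPM, the sulfite reductase subunit MET5 (chromosome 10, 678957 to 683285) had 256, 6.42, 77.9 and 3.18 TPM, and the ATP sulfurylase MET3 (chromosome 10, 456239 to 457774) had 142, 4.87, 46.5 and 1.39 TPM. Outside that list, the S-adenosylmethionine permease SAM3 (chromosome 16, 22938 to 24701) had 523, 16.8, 243 and 9.38 TPM and the biotin transporter VHT1 (chromosome 7, 618077 to 619858) had 129.5, 2.78, 54.0 and 1.37 TPM. AAD4, of the aryl-alcohol dehydrogenase family (chromosome 4, 17577 to 18566), had 486, 14.5, 205 and 8.02 TPM. The protein phosphatase PTC2 (chromosome 5, 335946 to 337340) had 174, 20.2, 59.1 and 0.424 TPM. Relative to the median gene PTC2 stood at 0.68, -0.21, 0.21 and -3.28, set apart by library 4. Coverage in library 4 was only 0.27 for PTC2, 0.74 for MMP1, 0.88 for MET3 and 0.86 for VHT1, so those values are uncertain. TRL1, the essential tRNA ligase (chromosome 10, 270002 to 272485), was listed at 58.3, 0, 22.5 and 4.41 TPM.

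Several genes fixed in advance belong to the thioredoxin system, which removes peroxides. TRX2, a thioredoxin, stood at 1735, 445, 1070.4 and 296 TPM, and its reductase TRR1 at 2256, 399, 1202 and 236 TPM. The peroxiredoxins TSA1 and AHP1 had 1052, 349, 497 and 144 TPM and 1632, 594, 961 and 319 TPM. Sulfiredoxin SRX1, which repairs oxidised peroxiredoxin, had 269, 258, 181 and 157 TPM, or -1.30, 0.79, -0.79 and 0.91 log2 units relative to the median gene, while GSH1, which starts glutathione synthesis, had 806, 65.8, 319 and 35.8 TPM. YAP1, the transcription factor of the peroxide response, had 244, 31.1, 93.5 and 19.3 TPM, the vacuolar glutathione-conjugate transporter YCF1 had 535, 20.5, 167 and 10.8 TPM, and OYE3 had 855, 23.4, 426 and 9.64 TPM. The catalase gene CTT1 was low, at 8.89, 14.2, 4.36 and 8.28 TPM. Relative to the median gene TRX2 stood at -0.29, -0.09, 0.09 and 0.15, and TSA1 at -0.28, 0.29, -0.28 and -0.16. TRR1 stood at 0.09, -0.25, 0.26 and -0.18, and AHP1 at -0.50, 0.19, -0.19 and 0.12. CTT1 stood at -1.57, 1.21, -1.37 and 1.32, GSH1 at 0.85, -0.59, 0.59 and -0.62, and OYE3 at 1.45, -1.53, 1.53 and -1.90. The TPM values of TRX2 and TSA1 thus mostly followed the messenger share of the libraries. As a list, the 37 peroxide and thiol defence genes stood apart in libraries 2 and 3 with all 4 libraries kept, with relative differences of 0.29, -0.36, 0.35 and -0.09. Its members split nearly evenly, with 19, 15, 22 and 18 of 37 above the median gene. Its share of TPM was 2.70, 0.455, 1.39 and 0.262%. In library 1 the list also stood apart against random lists matched on length, at 0.34, and among genes with a median TPM of at least 10, at 0.40. Its library 1 value was -0.11 without library 2, -0.092 without library 4 and 0.65, outside the central range, without library 3, where its library 4 value of 0.19 was also outside and opposite in sign to the main value.

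**Figure D3:**
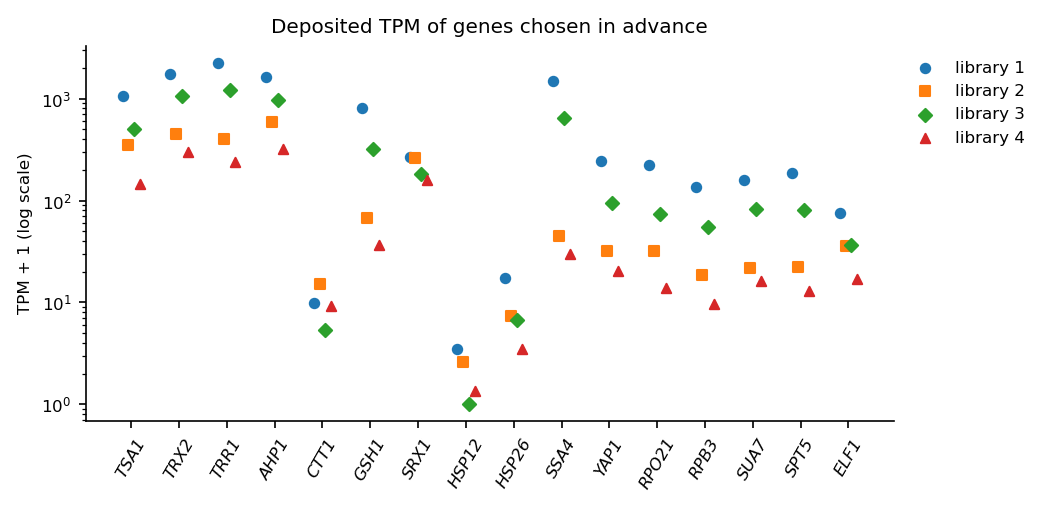
Deposited TPM plus 1 (log scale, y axis) of 16 genes chosen before the data were examined (x axis), with 1 symbol per library. TRR1 reached 2256 TPM in library 1, and HSP12 was listed at 0 in library 3.

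Heat shock chaperone genes stood above other genes of like level in libraries 1 and 3 and below them in libraries 2 and 4. Their relative differences were 1.28, -0.99, 0.99 and -0.80, and 19, 3, 18 and 2 of the 21 members lay above the median gene. Their shares were 2.51, 0.257, 1.02 and 0.127% of TPM. In library 1 the list median was 2.24, against 0.96 for random lists of like level and 1.61 for the median gene. The size of the 1.28 therefore depends on the genes of like level. These could include structural RNAs and ribosomal protein genes, described below, so the chaperone and ribosomal protein lists are not independent observations. With structural and mitochondrial RNA left out, the chaperone values were 0.74, -0.98, 0.68 and -0.88, all outside the central range. With length matched as well, the library 1 value was 0.45, also outside. SSA4, a stress-inducible Hsp70 (chromosome 5, 364589 to 366517), had 1496, 43.6, 641 and 28.9 TPM, and the Hsp90 gene HSP82 had 2742, 139, 1011 and 72.2 TPM. HSP26, a small heat shock protein gene, had 16.2, 6.36, 5.73 and 2.502 TPM. Relative to the median gene SSA4 stood at 1.53, -1.38, 1.39 and -1.14. HSP26 stood at -0.32, 0.60, -0.60 and 0.36, opposite to the chaperone list in each library. With gene length matched the list values were nearer 0, at 0.53, -0.61, 0.61 and -0.39, all still outside the central range. The library 1 value was 0.36 without library 2, 0.49 without library 4 and 2.34 without library 3, each outside. The library 4 value lay inside at -0.17 without library 1 and near 0 without library 3. The general stress list went the other way, at -0.29, 0.42, -0.42 and 0.40, with 12, 33, 6 and 30 of 39 members above the median gene. It held 0.732, 0.135, 0.308 and 0.0778% of TPM. Its member HSP12, a membrane-associated stress protein gene, was near 0 at 2.51, 1.58, 0 and 0.362 TPM, and TMA10 had 147, 6.64, 70.5 and 3.63 TPM. Relative to the median gene TMA10 stood at 1.05, -1.07, 1.08 and -0.97, opposite to this list in each library. SSA4 and HSP26 are also members of this list. The library 1 value of this list was inside the central range among genes with a median TPM of at least 10 (-0.21) and turned positive without library 2 (0.09) or library 4 (0.06). The library 4 value was 0.14 and inside without library 1, 0.15 without library 3 and 0.87 without library 2.

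With all 4 libraries kept, ribosomal protein genes stood below other genes of like level in libraries 1 and 3 and above them in libraries 2 and 4. The 137 genes had relative differences of -0.75, 0.56, -0.51 and 0.40, and 0, 135, 3 and 122 of them had positive values relative to the median gene. They held 2.74, 2.37, 1.71 and 1.11% of TPM, and 5.23, 17.9, 6.67 and 10.6% of TPM rescaled without structural and mitochondrial RNA, so library 1 went from the highest share to the lowest. The rescaled total still holds reading frames that overlap ribosomal RNA. In library 4 these held 4.26% of TPM against 5.77% for protein-coding genes, which lowers its rescaled share the most. RPS9A had 86.5, 32.7, 31.3 and 4.02 TPM and RPS22B had 79.9, 14.8, 48.5 and 9.78 TPM. Relative to the median gene RPS9A stood at -0.21, 0.57, -0.57 and -1.35, and RPS22B at -0.08, -0.28, 0.29 and -0.01. RPS9A thus went against the list in library 4 and RPS22B in libraries 2 and 3. Both were named for their large range and do not represent the list. Each has a near-identical partner gene, which makes single values uncertain. Against lists also matched on length the values were -0.46, 0.40, -0.36 and 0.30. Without library 3, the library 4 value was -0.13 and outside the central range in the opposite direction, so the higher position in library 4 depends on the libraries compared. Without library 1 the library 3 value was -0.11 and inside the central range, and without library 2 the library 1 value was -0.31 and outside.

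Ribosome biogenesis factors, which assemble the subunits, differed less, at 0.31, -0.11, 0.11 and -0.28, with 59, 19, 53 and 5 of 72 members above the median gene. Their share of TPM was 0.815, 0.128, 0.328 and 0.0547%. UTP10, of the small-subunit processome, had 181, 13.9, 52.2 and 5.07 TPM, and the helicase DBP8 had 84.6, 7.66, 32.4 and 2.20 TPM. In libraries 2 and 3 this list lay inside the central range once gene length was matched, at -0.04 and 0.04. Left-out libraries kept its calls in libraries 1 and 4 but moved the values, to between 0.16 and 0.51 and between -0.34 and -0.15. With structural and mitochondrial RNA left out, library 3 lay inside at 0.09, and outside at 0.14 when reading frames that overlap ribosomal RNA were also left out. The TCA cycle and respiration list had relative differences of -0.39, 0.35, -0.35 and 0.29, with 7, 35, 7 and 27 of 42 members above the median gene. It held 0.261, 0.0904, 0.124 and 0.0465% of TPM. LSC2, a succinyl-CoA ligase subunit, had 52.9, 8.43, 21.3 and 3.55 TPM, and the ATP synthase gene ATP5 had 86.7, 19.1, 23.3 and 6.76 TPM. Relative to the median gene LSC2 stood at 0.28, -0.08, 0.08 and -0.31, opposite to the list in each library. ATP5 stood at 0.38, 0.40, -0.40 and -0.14, opposite in libraries 1 and 4. The library 1 value of the list was inside the central range at -0.14 with length matched and at -0.12 without library 2. Its library 4 value was -0.03 without library 3 and 0.04 without library 1, both inside.

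Glycolysis, the pentose phosphate pathway and the proteasome did not stand apart in any library under the main setting. The 16 glycolysis genes had relative differences of 0.11, 0.20, -0.21 and -0.03, with 1, 16, 0 and 11 of 16 members above the median gene, which, unlike the random lists, is not matched on level. They held 1.63, 1.19, 0.737 and 0.445% of TPM, and 3.11, 8.94, 2.88 and 4.27% of TPM rescaled without structural and mitochondrial RNA, which put library 2 in place of library 1 as the highest. The rescaled total still holds reading frames that overlap ribosomal RNA, which lower the library 4 share the most. Hexokinase HXK2 had 739, 150.2, 252 and 52.2 TPM and the phosphofructokinase gene PFK2 had 293, 95.3, 109 and 37.3 TPM. With structural and mitochondrial RNA left out, glycolysis stood apart in library 2 at 0.55, a call lost at 0.42 when reading frames that overlap ribosomal RNA were also left out. With length matched it stood apart at 0.45 in library 2 and -0.45 in library 3. With length matched and structural and mitochondrial RNA left out, it stood apart at -0.26 in library 1, 0.85 in library 2 and 0.61 in library 4, the first and last opposite in sign to the main values. It also stood apart at 0.34 in library 1 without library 2, in library 3 at -0.38 without library 4, and in library 4 at -0.26 without library 1 and -0.48 without library 3. The 11 pentose phosphate genes held 0.151, 0.0338, 0.0625 and 0.0135% of TPM and had values of -0.42, 0.16, -0.16 and -0.04, with ZWF1, the NADPH-producing glucose-6-phosphate dehydrogenase, at 615, 68.3, 245 and 31.1 TPM and GND1 at 325, 71.9, 109 and 24.4 TPM. Matched on length, library 1 stood apart at -0.48, and library 4 did so at -0.35 without library 1. The 33 proteasome genes had 0.11, -0.12, 0.11 and -0.13 and held 0.639, 0.108, 0.280 and 0.0524% of TPM. Their regulator RPN4 had 380.3, 27.3, 113 and 13.5 TPM and RPN2 had 428, 40.3, 161 and 21.7 TPM. With length matched, the proteasome list stood apart at 0.22, -0.18, 0.18 and -0.17.

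The 12 RNA polymerase II subunit genes stood apart in library 4 alone, with relative differences of -0.23, -0.02, 0.01 and 0.29. They held 0.121, 0.0239, 0.0589 and 0.0145% of TPM. RPO21, the largest subunit, had 223, 30.9, 72.1 and 12.7 TPM, RPB2 had 219, 17.9, 81.5 and 10.2 TPM, and RPB3 had 134, 17.6, 53.5 and 8.73 TPM. In library 4 these genes stood at -0.45, -0.44 and -0.34 relative to the median gene, opposite to the list. The library 4 value of the list was 0.15 and inside the central range with length matched, and also inside without library 1 (0.19) or library 2 (0.37). Genes for 21 proteins targeted by ChIP-exo stood at 0.36, -0.20, 0.20 and -0.07, outside the central range in libraries 1, 2 and 3, and held 0.216, 0.0312, 0.0900 and 0.0160% of TPM. Among them, the initiation factor SUA7 had 159, 20.6, 81.4 and 15.1 TPM, the elongation factors SPT5 and ELF1 had 185, 21.3, 78.8 and 11.9 TPM and 73.9, 34.9, 35.8 and 15.96 TPM, the histone methyltransferase SET1 had 91.0, 6.27, 28.8 and 2.78 TPM, and the helicase SSL2 had 189, 13.4, 75.4 and 7.85 TPM. Relative to the median gene ELF1 stood at -0.57, 0.52, -0.52 and 0.27, opposite to this list. With length matched, the list lay inside in libraries 2 and 3 at -0.16 and 0.16, and in library 1 it did so without library 2 (0.070) or library 4 (0.078).

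The 35 other amino acid synthesis genes stood apart in library 4 alone, with relative differences of 0.05, -0.01, 0.01 and -0.19, and lay inside the central range after median-ratio scaling, at -0.07. The library 4 value was also inside with length matched (-0.09), with structural and mitochondrial RNA left out (-0.16) and without library 2 (-0.19). These genes held 0.533, 0.126, 0.230 and 0.0549% of TPM. ARG4, argininosuccinate lyase, had 292, 25.8, 162 and 12.1 TPM, and ARG8 had 46.9, 3.28, 21.4 and 1.30 TPM. The iron regulon stood apart in library 1 alone, at 0.37, -0.14, 0.15 and -0.21, and was inside at 0.20 after median-ratio scaling, with 0.242, 0.0385, 0.103 and 0.0181% of TPM. The library 1 value was also inside with length matched (0.21) and with structural and mitochondrial RNA left out (0.27). It was inside without library 2 (0.13), library 3 (0.52) or library 4 (0.15). The siderophore transporter SIT1 of this regulon had 155, 17.4, 57.3 and 6.57 TPM and the iron permease FTR1 had 319, 29.4, 184 and 14.9 TPM. The phosphate regulon stood apart in libraries 2 and 3, at -0.12, 0.42, -0.43 and -0.01, with 0.128, 0.0452, 0.0518 and 0.0170% of TPM. VTC2, of the polyphosphate polymerase complex, had 167, 19.8, 64.4 and 9.79 TPM, and the phosphate transporter PHO89 had 58.8, 8.78, 21.5 and 2.90 TPM. Relative to the median gene VTC2 stood at -0.29 and 0.29 in libraries 2 and 3 and PHO89 at -0.06 and 0.06, opposite to the list. Without library 2, the phosphate regulon values in libraries 1 and 4 were 0.24 and 0.61, both higher than the central range. In the opposite direction, library 1 was lower at -0.36 with length matched, and library 4 was lower at -0.44 without library 3.

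Under the main setting, with all 4 libraries kept, the G2/M genes stood apart in each library and the other cell cycle lists in none. The G2/M values were 0.62, -0.26, 0.26 and -0.34, with 0.0384, 0.00369, 0.0134 and 0.00137% of TPM. The polo kinase CDC5 had 59.3, 4.14, 19.3 and 0.955 TPM and the deacetylase HST3 had 53.4, 3.49, 26.6 and 1.33 TPM. Among genes with a median TPM of at least 10, libraries 2 and 3 lay inside, at -0.36 and 0.36, and library 4 lay inside without library 1 (-0.19) or library 3 (-0.14). G1/S genes, with 0.0434, 0.00863, 0.0172 and 0.00302% of TPM, had 0.05, 0.24, -0.23 and -0.17, with the replication factor RFA1 at 79.5, 10.8, 27.9 and 3.27 TPM and ribonucleotide reductase RNR1 at 113, 16.01, 40.9 and 5.79 TPM. The library 4 value stood apart at -0.42 with structural and mitochondrial RNA left out, a call lost at -0.32 when reading frames that overlap ribosomal RNA were also left out. It also stood apart at -0.44 among genes with a median TPM of at least 10, at -0.35 with FPKM, at -0.32 without library 1 and at -0.36 without library 3. M/G1 genes, with 0.0824, 0.0176, 0.0308 and 0.00643% of TPM, had 0.06, 0.06, -0.06 and -0.22, with the daughter-cell genes DSE4 at 80.1, 6.86, 24.6 and 1.98 TPM and DSE1 at 195, 20.9, 77.2 and 8.72 TPM, and stood apart in library 4 at -0.36 without library 1 and -0.37 without library 3. Histones, with 0.259, 0.0823, 0.172 and 0.0449% of TPM, had -0.45, 0.08, -0.09 and 0.12, with the histone H3 genes HHT1 and HHT2 at 706, 136, 501 and 70.9 TPM and 644, 148, 348 and 69.8 TPM, and stood apart in library 1 at -0.36 without library 2. Meiosis and sporulation genes, of which 7 of 15 passed the expression filter, had 0.29, 0.14, -0.13 and -0.20 and held 0.00601, 0.00173, 0.00271 and 0.000638% of TPM.

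Genes of the a mating type were expressed. The receptor STE2 had 384, 34.3, 167 and 16.8 TPM, the pheromone exporter STE6 had 297, 21.9, 105 and 9.97 TPM, and the protease BAR1 had 221, 16.5, 103.8 and 10.1 TPM. The pheromone genes MFA1 and MFA2 had 71.7, 44.8, 49.2 and 24.1 TPM and 149, 70.6, 124 and 62.4 TPM, AGA2 had 37.5, 13.01, 24.7 and 10.3 TPM, and ASG7 had 12.5, 5.61, 10.5 and 1.68 TPM. As a list they held 0.117, 0.0207, 0.0585 and 0.0135% of TPM and had relative differences of -0.57, 0.05, -0.06 and -0.24, inside the central range. The library 1 call differed between settings. It was lower at -0.60 with structural and mitochondrial RNA left out, at -0.49 with length matched as well, and at -0.50 without library 2, and inside at -0.56 when reading frames that overlap ribosomal RNA were left out too. In library 4 the list was lower at -0.48 with a pseudocount of 0.1 and had a value of 0.26, inside, with a pseudocount of 5. Of the alpha-type genes, STE3 was listed at 0.169, 0, 0 and 0.0451 TPM, MF(ALPHA)1 was listed at 0 in each library, MF(ALPHA)2 had 31.3, 1.81, 15.2 and 0.693 TPM, and SAG1 had 12.7, 4.26, 4.99 and 2.08 TPM. These 4 genes held 0.00442, 0.000607, 0.00202 and 0.000282% of TPM, and only 2 of them passed the filter, too few for a list difference. Among common marker loci, LEU2, URA3 and MET17 were listed at 0 in all 4 libraries. HIS3 had 24.3, 6.91, 10.2 and 5.20 TPM, TRP1 had 23.7, 9.14, 16.1 and 3.67 TPM, ADE2 had 121, 19.8, 51.0 and 8.24 TPM, LYS2 had 109, 11.6, 37.7 and 4.79 TPM, and CAN1 had 105, 12.98, 35.9 and 6.47 TPM. The 5 tested marker genes had relative differences of 0.14, -0.06, 0.06 and -0.10, and all 8 loci held 0.0384, 0.00605, 0.0151 and 0.00284% of TPM.

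Transcripts of the mitochondrial genome stood low in libraries 1 and 3 and high in libraries 2 and 4 against other genes of like level, at -1.20, 1.15, -1.43 and 0.95 over 16 tested genes, and held 0.0241, 0.0586, 0.0138 and 0.0230% of TPM. The mitochondrial 15S_RRNA (mitochondrial genome, 6546 to 8194) had 30.8, 131, 13.4 and 41.7 TPM, and the mitochondrial tRNA gene tT(UGU)Q1 (mitochondrial genome, 63862 to 63937) was listed at 0, 43.6, 27.99 and 0 TPM. The calls of the mitochondrial list held whichever library was left out. With no expression filter, most of the 55 mitochondrial entries were near 0 and the list value was 0 in each library. The 242 tested structural RNA genes had relative differences of -1.66, 0.92, -0.45 and 1.16. The library 2 value was 0.047 without library 1 and 0.051 without library 3, and the library 3 value was 0 without library 2 or library 4.

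Library differences also followed gene length. Across the 6400 genes, the Spearman correlation of length with the difference between the first and second library named was 0.479 for libraries 1 and 2, 0.650 for 1 and 3, 0.550 for 1 and 4, -0.227 for 2 and 3, 0.177 for 2 and 4, and 0.338 for 3 and 4. With structural and mitochondrial RNA left out, the correlations were weaker in each pair, at 0.379, 0.585, 0.453, -0.156, 0.168 and 0.260 in the same order. Long genes were thus relatively higher in library 1 than in each of the others under both settings.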

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

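The tests on structural RNA and the per-gene listing of zeros were chosen after the results were seen, while the predictions for gene length were written before the length-matched lists were drawn. Of 135 sets of 4 library values, 1 had a library far from the others, where chance marks about 1 in 20. TRL1, relative to the median gene, stood at 0.78, -2.95, 0.52 and 0.31 log2 units (Dixon ratio 0.873), set apart by the 0 listed in library 2.

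With all libraries in the reference median, the ribosomal protein and heat shock lists stood apart in 4 of 4 libraries each, in opposite directions, but these calls depend on the libraries kept. Without library 3 the ribosomal proteins were lower in library 4 (-0.13), the opposite call, and heat shock there was near 0, and without library 1 the ribosomal proteins lay inside in library 3 (-0.11) and heat shock in library 4 (-0.17). Gene length as the whole cause would have placed both inside the central 95% of lists matched on level and length, and each stayed outside in 4 libraries. With length matched, the heat shock value in library 1 went from 1.28 to 0.53 and the ribosomal protein value from -0.75 to -0.46. The list medians did not change, while those of the random lists went from 0.96 to 1.71 and from 1.26 to 0.97. Length may account for part of the difference, but this change cannot show it, because random lists could contain members of either list. For the same reason the opposite directions are not independent. A length effect within the 5 bins stays open, GC content was not tested, and no biological explanation was tested, because the labels give no groups.

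The structural RNA share ran from 47.5% to 89.5% of TPM. If 5.8S rRNA alone were the cause, the other structural RNAs would keep a steady ratio to the remaining nuclear TPM, but that ratio still differed 9.92-fold between the highest and the lowest library, and 16.03-fold over protein-coding TPM without reading frames that overlap ribosomal RNA. If a higher yield of short RNAs alone were the cause, the long 18S and 25S rRNAs would keep theirs, and it differed 4.70-fold and 5.53-fold over the same denominators. A difference in ribosomal RNA removal or messenger selection between libraries, and a lower messenger content of the cells, may each give such a shift, and neither was tested. No biological explanation was tested here either.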

How the results depend on the processing

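Length matching, the handling of reading frames that overlap ribosomal RNA and the pairwise differences were chosen after seeing the data, and the other alternatives before. Of the 46 list-library values outside the central range, 44 kept their call with a pseudocount of 0.1, 42 with 5, 41 with no filter, 43 with a minimum median TPM of 10, 44 with median-ratio scaling and 45 with FPKM. Without structural and mitochondrial RNA 35 of 38 did, and with length matched 38 of 46 did, with 9 gained. None of these changed the sign of a call, although with no filter the 4 mitochondrial values were 0. With length matched and structural and mitochondrial RNA left out, glycolysis was -0.26 in library 1 and 0.61 in library 4, opposite to the main values. Leaving out libraries 1, 2, 3 and 4 in turn kept 20 of 35, 17 of 34, 19 of 34 and 22 of 35 calls, with 9, 11, 10 and 10 of the lost ones at 0, where the middle of 3 libraries sits, and 1 opposite call. Including gained ones, 22 to 26 of 72 values stood apart. Ranges over the left-out libraries were -0.13 to 1.11 for ribosomal proteins in library 4, -0.11 to 0.65 and -0.30 to 0.19 for peroxide defence in libraries 1 and 4, -0.68 to 0.085 for general stress in library 1, -0.031 to 0.55 for respiration in library 4, and -0.71 to 0.24 and -0.44 to 0.61 for the phosphate regulon in libraries 1 and 4. Each changed sign in at least 1, as the reference median changes with the libraries kept. Genes spanning 2-fold numbered 6286, against 2715 with median-ratio scaling, 4784 without structural and mitochondrial RNA, 3479 with the overlapping reading frames also left out, and 3838 of 3896 tested at a minimum median TPM of 10. The median range was 0.88 with median-ratio scaling and 1.44 without structural and mitochondrial RNA. At a minimum median TPM of 10, Spearman correlations were 0.586 for libraries 1 and 2, 0.571 for 1 and 4, 0.663 for 2 and 3 and 0.690 for 3 and 4, and the length correlation of libraries 1 and 3 was 0.762; the cause was not tested. Rescaling moved 23 list shares, as their denominator changed. FPKM shares equal TPM shares by construction, no repeated gene names existed for the planned choice between them, and GC content was not run. The low median depth of library 4 limits its values for most genes. Of 86 named genes tested, 25 no longer spanned 2-fold with median-ratio scaling.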

Other observations

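The families, genes and pairwise values in this part were chosen after the results were seen. Drug efflux transporters stood apart in each library, with relative differences of 1.20, -0.62, 0.61 and -0.67 over 9 genes. The ABC transporters PDR5 and SNQ2 had 2493, 207, 792 and 103 TPM and 1894, 155, 618 and 85.6 TPM, and FLR1, a multidrug transporter, had 1753, 96.8, 828 and 63.4 TPM. ATR1 had 505, 26.6, 214 and 15.4 TPM, while PDR10 had 13.4, 2.84, 6.34 and 1.10 TPM. FLR1 and ATR1 also belong to the peroxide and thiol defence list. The aryl-alcohol dehydrogenase family had 0.87, -0.42, 0.43 and 0.11 over 5 tested genes, outside the central range in libraries 1, 2 and 3, and AAD3 had 151, 6.97, 47.3 and 2.86 TPM. AAD4 belongs to this family and had prompted its choice.

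Translation factors, with 17 genes, had -0.09, 0.32, -0.33 and 0.00 and lay inside the central range in each library. Pair by pair they stood apart once, higher in library 2 than in library 4 by 0.37. YEF3, an elongation factor, had 965, 313, 307 and 94.2 TPM and the initiation factor TIF1 had 246, 87.2, 93.5 and 33.7 TPM. The 18 cytosolic aminoacyl-tRNA synthetase genes also lay inside, at 0.14, 0.14, -0.15 and -0.18, but stood apart in 2 pairs, higher in library 1 than 3 by 0.20 and in library 2 than 4 by 0.34. Glycolysis stood apart in the same 2 pairs, by 0.44 and 0.46.

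Taken pair by pair, the libraries fell into 2 sets of alike libraries. Spearman correlation was 0.952 for libraries 1 and 3 and 0.900 for 2 and 4, against 0.757, 0.760, 0.793 and 0.818 for 1 and 2, 1 and 4, 2 and 3, and 3 and 4. Heat shock chaperones differed, first library minus second, by 0.39 for 1 and 3 and -0.05 for 2 and 4, against 2.25, 2.12, -1.98 and 1.90 for the other pairs in that order. Ribosomal proteins differed by -0.26 and 0.21, against -1.22, -1.19, 1.10 and -0.83. Part of the library composition split the same way, with 5S rRNA at 0.230, 6.06, 0.410 and 6.15% of TPM, structural RNA at 21.7, 65.8, 39.7 and 74.6% of bases and a median protein-coding coverage of 12.8, 3.70, 8.17 and 2.26 in libraries 1 to 4. Other parts did not. The 25S rRNA held 3.15, 3.38, 1.92 and 1.77% of TPM, 5.8S rRNA 40.6, 69.7, 68.3 and 75.8%, and reading frames that overlap ribosomal RNA 1.57, 0.311, 1.92 and 4.26%. Composition and any condition cannot be told apart here, so the sets were not assigned to conditions. The labels do not say what separates the sets. The number of lists that stood apart did not separate the sets, at 11 of 24 for libraries 1 and 3 and 11 for 2 and 4, against 12, 10, 12 and 9 for the other pairs.

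Some entries of 0 fell in genes with reads elsewhere. In all, 13 protein-coding genes were listed at 0 in a single library with a coverage of at least 1 in the other 3, of which 5 were in library 2, 1 in library 3 and 7 in library 4. TRL1, required for tRNA splicing in every cell, was at 0 in library 2, where its neighbours EXO70 and ALY2 had 5.05 and 5.07 TPM. The copper transporter CTR2 had 39.2, 14.5, 23.9 and 0 TPM and SSH4 had 31.2, 0, 13.04 and 3.69 TPM. Of the nuclear protein-coding genes, 34 were at 0 in all 4 libraries, among them LEU2, URA3 and MET17.

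Reading frames that overlap ribosomal RNA held 1.57, 0.311, 1.92 and 4.26% of TPM, nearly all of it outside the 46.9, 12.2, 21.2 and 5.77% of nuclear protein-coding genes. YLR154W-E alone was listed at 14859.6, 2902, 18643 and 42464 TPM.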
